A study of Mus musculus with 8 samples.

How the data were processed

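RNA was sequenced from 8 libraries of hemogenic endothelium, the endothelial cells that give rise to blood cells, made in culture from mouse embryonic stem cells. Per the labels' protocols, FLK1-positive cells were taken from embryoid bodies at day 3.25, kept for 2 days in liquid blast culture, and sorted as cells positive for cKIT and TIE2 and negative for CD41. Total RNA was depleted of ribosomal RNA and made into libraries with a SOLiD total RNA kit, per the labels' protocols, and the series' design text names the SOLiD 5500XL sequencer. The iDam and BryGFP lines carried functional Runx1 (wt), and the iDamko and Ainv18ko lines were Runx1 knockouts (ko), with 2 libraries per line that the design text calls biological duplicates.

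The deposited data analysed here were 1 table of 622 genes. The submitters' processing notes name edgeR and the mm9 genome build, with no version for edgeR, and the aligner, the counting step and the gene annotation were not given in the sources used here. The authors gave 2 comparisons, of the 4 ko libraries with iDam and of the same 4 ko libraries with BryGFP, and for each the table holds a log2 fold, a mean log2 CPM, a p-value and an FDR. Every gene in the table had an FDR under 0.05 in both comparisons, with a highest FDR of 0.049 for iDam and 0.05 for BryGFP, and the same direction in both. The signs of the deposited log2 folds matched wt over ko in all 622 genes, so folds are given below with the direction stated in words. The deposited values per library carry no unit name in the file header, and their scale was settled from the values as RPKM, read counts scaled by gene length and library size. The gene length that the authors' deposited CPM and RPKM imply correlated with annotated exon length across 444 genes (Pearson r = 0.909), where genes are not independent replicates.

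The columns of the table name lines and not individual samples, and each column was mapped to its line by name, with Ainv18ko assigned as the knockout line without the Dam tag. The 4 ko columns stand in the table a second time with identical values and were used once. Low values of small RNAs and weakly expressed genes fell on whole multiples of 1 read, within 0.06 of a read for 83.3% to 100% of the 13 to 36 values used per library. These steps imply depths of 42340000 to 58940000 reads per library, an estimate that covers counting only. The ranks behind the deposited p-values and FDRs imply that the authors tested 37620 genes in each comparison. At least 1737 genes then passed their FDR threshold against iDam and at least 1601 against BryGFP, and genes outside the table were not analysed here.

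RPKM values were tested with limma 3.58.1 in R 4.3.3, with a mean-variance trend, on log2(RPKM + 1), after keeping the 360 genes with a mean of at least 1 RPKM over the 8 libraries. Log2 differences on this scale understate the change of weakly expressed genes. P-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The comparison of ko with wt took the 4 libraries of each genotype as replicates. A model with 1 mean per line and a spread shared over all 8 libraries gave iDamko against iDam, Ainv18ko against BryGFP, the difference between these effects, and the comparisons of lines of 1 genotype. Count tests had been planned for count tables and were not used, since the values were RPKM. All 622 genes had been selected by the authors as differing between ko and wt on the same libraries, so tests of ko against wt within the table are not independent evidence, and their adjusted p-values describe only size against spread.

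On simulated data with the spread of the 360 genes, limma recovered 97% of genes changed by 1 and 100% of genes changed by 2 on the log2 scale for ko against wt, with 11 false calls. For iDamko against iDam it recovered 80% and 99%, with 6 false calls, and for the difference between the ko effects it made 0 false calls. Most of the 360 genes were simulated as changed, so the false calls come from the smaller rest. The simulated spread was that within lines, and lines of 1 genotype did not differ. In the real data 91 genes passed between the wt lines, so the rates for ko against wt do not carry over to it.

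Before the data were examined, 20 gene lists were fixed, covering integrins, cell-cell adhesion molecules, extracellular matrix and its proteases, migration and actin signalling, guidance and angiogenic cues, blood transcription factors, the Notch and TGF-beta/BMP pathways, cell cycle, cytokine receptors, sort markers, and markers of endothelial, erythroid, megakaryocyte, myeloid, smooth muscle, cardiac, pluripotent, endoderm and neural cells. Each list's split between genes lower and higher in ko was compared with that of the other genes in the table by a two-sided Fisher's exact test, adjusted over the 19 lists with a member in the table. The genes named were also set by a rule fixed then: in each comparison, the 5 largest changes in each direction among genes above the median level, the 3 largest in each direction per list, and Runx1, Kit, Tek, Itga2b, Gfi1, Gfi1b and Spi1. Of these last, only Gfi1 was analysed here. Genes named outside the rule are said to be so where they appear.

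Positions are from the GENCODE M21 annotation of GRCm38, matched by gene identifier for 612 of the 622 genes. These coordinates differ from those of mm9 and were not converted. One symbol that a spreadsheet had turned into a number was read by its identifier. Genes that share sequence with a near-identical copy are uncertain, because the treatment of shared reads was not given in the sources used here. These include 15 SNORD113 entries, the Ugt1a genes, Glul with its pseudogene Glns-ps1, the Mir196a-1 entries, and Mir675, which lies within H19. The same holds for overlapping and antisense genes, for which strand use was not stated.

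Alternatives included quantile normalization, the scaling implied by the authors' folds, a pseudocount of 0.1, no filter on level, line means as replicates, a threshold of 0.01, a minimum change of 1 on the log2 scale, fits to the 4 libraries of a pair, a block for the number in the column names, and leaving out each library in turn. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.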

Results

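Gene expression was compared between Runx1 knockout and wt hemogenic endothelium, 4 libraries each, to ask which genes depend on RUNX1, a transcription factor needed for blood cells to emerge from endothelium, with adhesion and migration genes as the stated interest. The wt libraries came from the embryonic stem cell lines iDam and BryGFP and the ko libraries from iDamko and Ainv18ko, 2 libraries per line. Depths implied by the values were 53080000 and 42340000 reads for iDam, 44460000 and 51900000 for BryGFP, 47000000 and 58940000 for iDamko, and 44440000 and 42380000 for Ainv18ko. Runx1 itself was not analysed here, so the genotypes are those of the labels, with no check on the targeted transcript.

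Of the listed genes that were in the table, 3 of 4 integrin genes, all 11 matrix genes and all 3 cell-cell adhesion genes were lower in ko cells, while the activin antagonist gene Fst was higher, as were all 4 erythroid and 5 of 7 cardiac genes. The lists held 26 integrin, 63 matrix, 43 cell-cell adhesion, 22 erythroid and 27 cardiac genes, most of them outside the table. Of all genes in the table, 62.2% were lower in ko. No gene list passed the test of its direction against the other genes of the table (lowest adjusted p = 0.164, Fisher's exact test). The integrin subunit gene Itgb3 (ENSMUSG00000020689; chromosome 11, 104608000 to 104670476, GRCm38) was at 4.74 ± 2.94 RPKM in wt and 0.255 ± 0.126 in ko (SD, n = 4). Itga3, a laminin-binding integrin subunit, was at 20.9 ± 5.70 RPKM in wt and 3.89 ± 0.637 in ko (SD, n = 4). Fst (chromosome 13, 114452290 to 114458951, GRCm38) went the other way, from 0.305 ± 0.101 RPKM in wt to 23.6 ± 11.9 in ko (SD, n = 4). In the authors' deposited table, Itgb3 was 8.20-fold lower in ko against iDam and 27.8-fold lower against BryGFP, Itga3 was 4.06-fold and 6.38-fold lower, and Fst was 108-fold and 62.2-fold higher.

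Of the 622 genes in the authors' deposited table, 387 were lower in ko and 235 higher, in both comparisons. Above the median level of the table, 153 were lower and 158 higher. The median fold in the authors' deposited table was 3.87 against iDam and 4.23 against BryGFP for genes lower in ko, and 3.42 and 2.67 for genes higher in ko. In 618 genes (99.4%) the RPKM of the 4 ko libraries lay entirely on one side of the 4 wt libraries, where chance gives 2.86%, although the genes had been selected for this difference. Both comparisons used the same 4 ko libraries. Simulated unchanged genes with that sharing passed both comparisons with 1 sign 1.56 times per run on average, at most 5 times in 100 runs, and independent lists of at least the authors' sizes would share at least 73.9 genes, at least 37.0 of them with the same direction, since these sizes are known only as lower bounds. The simulation drew each library independently, with no differences between lines of 1 genotype, while 91 of the 360 tested genes passed between the wt lines. The 1.56 is therefore not the number that lines differing for reasons other than Runx1 would give. Parts of the overlap above these values may rest on the shared libraries or on differences between lines.

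**Figure D1:**
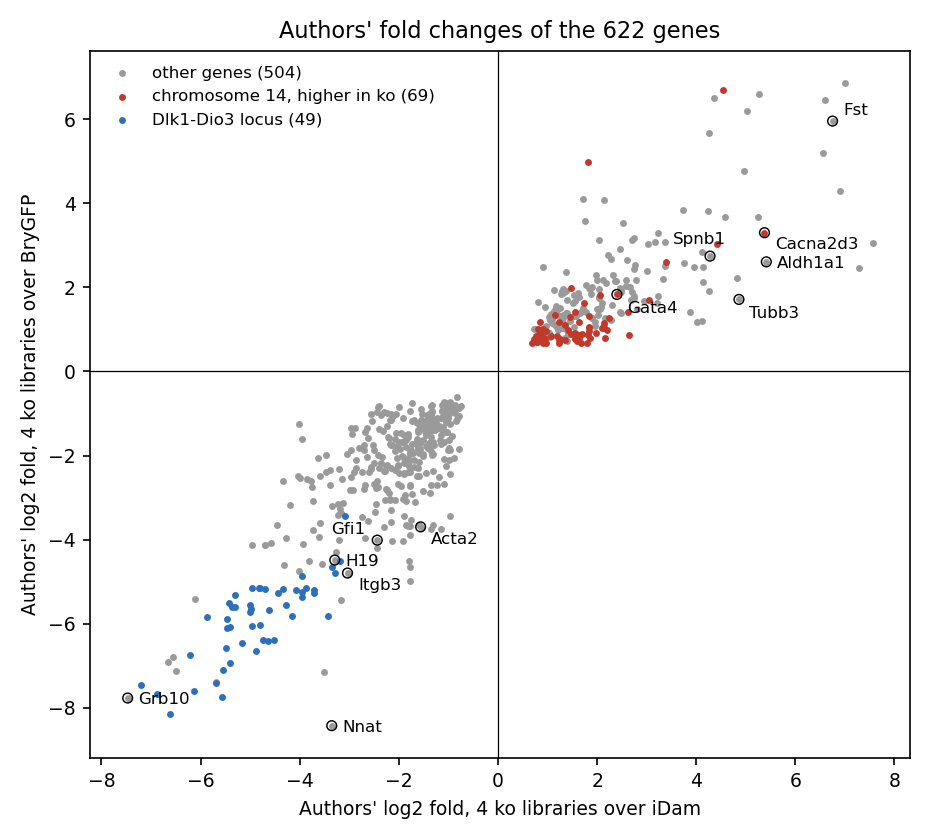
The authors' log2 folds of the 622 genes, ko over iDam (x axis) against ko over BryGFP (y axis), each point 1 gene. Genes lower in ko lie at lower left and genes higher in ko at upper right; blue points are transcripts of the Dlk1-Dio3 locus (49) and red points genes higher in ko on chromosome 14 (69).

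Extracellular matrix genes and proteases went in 1 direction: all 11 members in the table were lower in ko. The gelatinase gene Mmp2 was at 27.8 ± 7.73 RPKM in wt and 5.13 ± 1.12 in ko (SD, n = 4), and the fibrillar collagen gene Col5a1 at 26.2 ± 14.3 and 6.94 ± 1.57 (SD, n = 4). The urokinase gene Plau, which lies on chromosome 14, was at 7.49 ± 3.73 RPKM in wt and 2.28 ± 0.303 in ko (SD, n = 4). In the authors' deposited table, the weakly expressed Adamts4 was 6.47-fold lower in ko against iDam and 3.65-fold lower against BryGFP, and Col6a1 4.61-fold and 7.37-fold lower. The matrix list had an unadjusted p of 0.00862 by Fisher's exact test, which became 0.164 after adjustment over the 19 lists, so its direction was not set apart from that of the table.

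Of the 4 integrin genes in the table, 3 were lower and 1 higher in ko. Itgb5 was at 7.49 ± 3.63 RPKM in wt and 2.20 ± 0.600 in ko (SD, n = 4), and the leukocyte integrin gene Itgb2 at 0.535 ± 0.210 and 2.35 ± 1.26 (SD, n = 4). All 3 cell-cell adhesion molecules in the table were lower in ko. The tight junction gene Cldn5 was at 13.1 ± 7.53 RPKM in wt and 3.08 ± 0.860 in ko, the endothelial lectin gene Clec14a at 9.84 ± 6.12 and 2.64 ± 0.299, and the cadherin gene Cdh11 at 9.71 ± 8.14 and 1.48 ± 0.340 (SD, n = 4 each). The adjusted p by Fisher's exact test was 1 for integrins and 0.822 for cell-cell adhesion molecules.

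Migration and actin genes in the table split, 5 lower and 3 higher in ko. The adaptor gene Nedd9 was at 3.72 ± 0.935 RPKM in wt and 0.911 ± 0.406 in ko (SD, n = 4), and the actin-severing gene Gsn at 4.84 ± 3.05 and 0.919 ± 0.236 (SD, n = 4). Fermt3, which encodes the integrin activator kindlin-3, was higher in ko, at 80.2 ± 25.9 RPKM against 25.3 ± 6.58 (SD, n = 4). The focal adhesion kinase family gene Ptk2b, on chromosome 14, was at 3.32 ± 0.0976 RPKM in ko and 0.743 ± 0.362 in wt (SD, n = 4). Lcp2, in the authors' deposited table, was 13.4-fold lower in ko against iDam and 6.77-fold lower against BryGFP, and Was 4.00-fold and 5.35-fold lower. Among the guidance and angiogenic cues that the table holds, 6 were lower and 3 higher. The apelin receptor gene Aplnr was at 39.8 ± 11.2 RPKM in wt and 9.94 ± 4.36 in ko, and the ephrin receptor gene Ephb2 at 5.96 ± 2.69 and 1.09 ± 0.287 (SD, n = 4 each). In the authors' deposited table, Angpt2 was 5.02-fold lower in ko against iDam and 2.66-fold lower against BryGFP, and Fgf2 6.06-fold and 6.30-fold higher. The adjusted p by Fisher's exact test was 1 for migration genes and 1 for guidance genes.

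All 3 blood transcription factors in the table were lower in ko. Gfi1 (ENSMUSG00000029275; chromosome 5, 107716657 to 107726036, GRCm38), a repressor acting in the transition from endothelium to blood, was at 3.13 ± 1.78 RPKM in wt and 0.285 ± 0.0697 in ko (SD, n = 4). In the authors' deposited table, Gfi1 was 5.41-fold lower in ko against iDam and 16.1-fold lower against BryGFP, and Hoxa9 18.3-fold and 8.98-fold lower. Ikzf2 was at 2.84 ± 0.824 RPKM in wt and 0.791 ± 0.345 in ko (SD, n = 4). The adjusted p by Fisher's exact test for this list was 0.822.

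Members of the signalling lists that were in the table moved in both directions. In the TGF-beta/BMP list 2 were lower and 2 higher: Bmp4, on chromosome 14, was at 21.9 ± 11.3 RPKM in wt and 3.58 ± 1.38 in ko, and the BMP-binding gene Bmper at 2.90 ± 0.817 and 8.26 ± 2.46 (SD, n = 4 each). In the Notch list 2 were lower and 1 higher, with the fringe gene Mfng at 2.11 ± 1.40 RPKM in wt and 0.153 ± 0.110 in ko, and the ligand gene Jag2 at 2.43 ± 0.747 and 5.38 ± 0.793 (SD, n = 4 each). Of the 38 genes of the cell cycle list only 2 were in the table, both lower, the cyclin D1 gene Ccnd1 at 34.1 ± 10.0 RPKM in wt and 8.74 ± 5.31 in ko, and Cdkn2a at 9.23 ± 3.29 and 1.90 ± 0.601 (SD, n = 4 each). Of the cytokine receptors in the table, Il4ra was lower in ko and Il1r1 higher. The adjusted p by Fisher's exact test was 1 for each of these 4 lists.

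Some markers of other cell types were also in the table, and the counts below cover only these. All 4 erythroid genes were higher in ko: the erythroid spectrin gene Spnb1 at 20.4 ± 4.16 RPKM in ko and 2.16 ± 1.26 in wt, the heme synthesis gene Alas2 at 11.1 ± 3.69 and 1.38 ± 0.740, the transferrin receptor gene Tfrc at 63.0 ± 6.49 and 24.9 ± 7.54, and Car2, named after its values were seen, at 55.0 ± 11.7 and 30.4 ± 1.48 (SD, n = 4 each). All 4 smooth muscle and mesenchyme genes were lower in ko, with the smooth muscle actin gene Acta2 at 40.5 ± 25.4 RPKM against 334 ± 250 in wt and Pdgfrb at 0.918 ± 0.362 against 7.53 ± 6.10 (SD, n = 4 each). Of the cardiac genes 5 were higher and 2 lower, with the transcription factor gene Gata4, on chromosome 14, at 43.8 ± 3.97 RPKM in ko and 10.7 ± 2.72 in wt, and Hand1 at 1.14 ± 0.692 and 11.9 ± 8.69 (SD, n = 4 each). Both neural genes were higher, Tubb3 at 54.2 ± 28.1 RPKM in ko and 9.25 ± 8.51 in wt, and the neurofilament gene Nefl, on chromosome 14, at 34.1 ± 10.4 and 2.94 ± 1.78 (SD, n = 4 each). Endothelial markers were lower for 3 genes and higher for 1, and myeloid markers lower for 2 and higher for 1. The megakaryocyte list held Itgb3, the pluripotent list Dppa4, which was lower in ko, and the endoderm list Foxa2, which was higher. The adjusted p by Fisher's exact test was 0.190 for erythroid (unadjusted 0.0201), 0.822 for smooth muscle, 0.676 for cardiac, 0.676 for neural, 0.897 for endoderm, and 1 for the endothelial, myeloid, megakaryocyte and pluripotent lists. The sort markers Kit, Tek and Itga2b were not analysed here.

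The imprinted growth regulator gene Grb10 (chromosome 11, 11930508 to 12038683, GRCm38) had a mean of 100 ± 18.3 RPKM in wt and 0.484 ± 0.225 in ko (SD, n = 4). In the authors' deposited table it was 177-fold lower in ko against iDam and 218-fold lower against BryGFP, with FDR values of 1.85e-98 and 6.71e-105. The imprinted noncoding RNA H19 was at 62.2 ± 27.2 RPKM in wt and 3.76 ± 2.69 in ko (SD, n = 4). The glutamine synthetase gene Glul was at 288 ± 133 RPKM in ko and 39.7 ± 8.71 in wt (SD, n = 4), with shared reads possible between it and its pseudogene Glns-ps1.

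**Figure D2:**
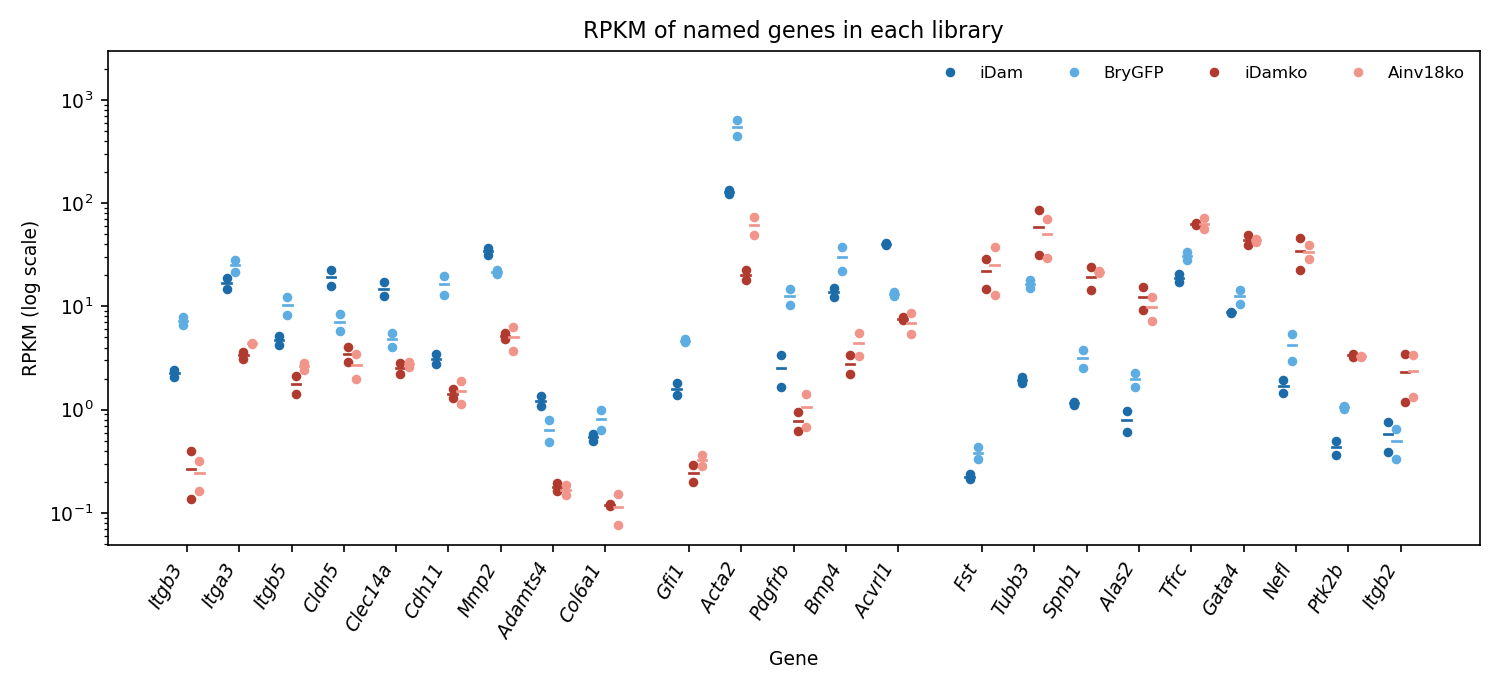
RPKM (log scale) of named genes in each of the 8 libraries, with each point 1 library and each bar the mean of the 2 libraries of a line. For Itgb3, Gfi1 and Fst the 4 ko libraries (reds) stand clear of the 4 wt libraries (blues), while Acta2, Cdh11 and Acvrl1 also differ between the wt lines.

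Genes of both directions were unevenly placed in the genome. Of the 235 genes higher in ko, 69 (29.4%) lay on chromosome 14, against 4 (1.03%) of the 387 lower in ko, and this chromosome holds 4.11% of annotated protein-coding genes. Fisher's exact test of direction for chromosome 14 gave a Benjamini-Hochberg p of 2.68e-26. The 69 included Gata4, Nefl and Ptk2b, while Bmp4 and Plau were among the 4 that were lower. Without chromosome 14, 383 genes were lower and 166 higher in ko. Of the genes lower in ko, 56 (14.5%) lay on chromosome 12, most of them in the imprinted Dlk1-Dio3 locus. That chromosome holds 2.93% of annotated protein-coding genes (Fisher's exact test of direction, Benjamini-Hochberg p = 0.000412). Without imprinted genes and this locus, 328 genes were lower and 235 higher in ko. From position 60784573 to 79423587 (GRCm38), a stretch chosen after its values were seen, 27 of the genes higher in ko, Gata4, Nefl and Ptk2b among them, had a median ratio of iDam to BryGFP RPKM of 0.539 (quartiles 0.478 and 0.616). The ratio was 0.998 (quartiles 0.894 and 1.08) over the other 41 such genes of the chromosome.

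**Figure D3:**
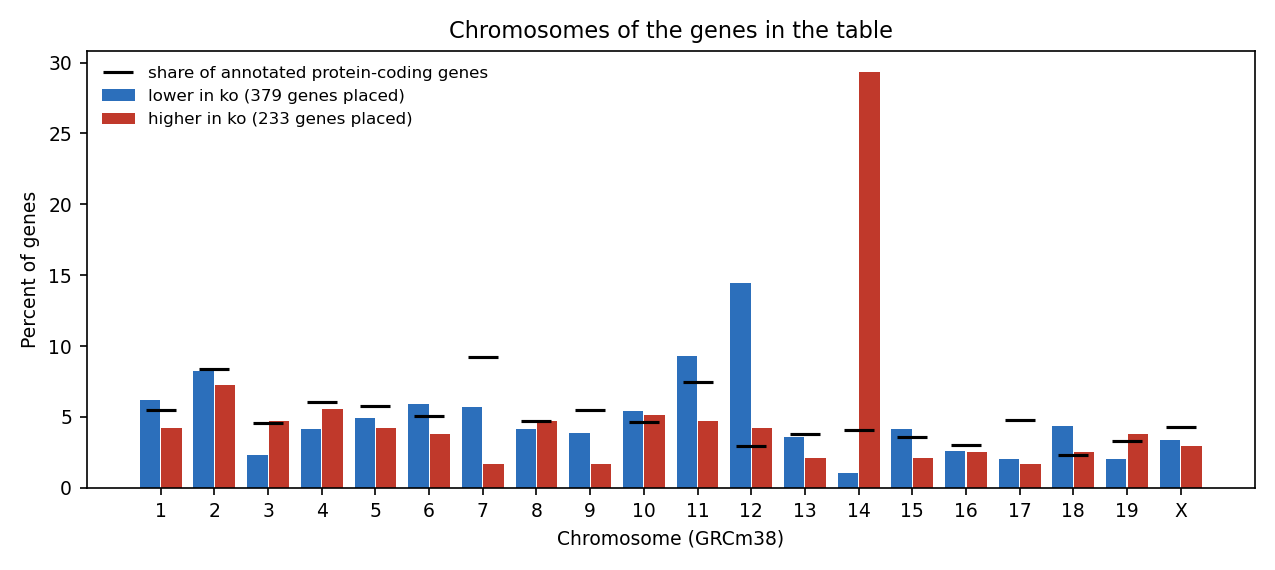
Share of genes lower in ko (blue) and higher in ko (red) on each chromosome, in percent of the 387 and 235 genes, of which 379 and 233 had a position on GRCm38, with black bars for the share of annotated protein-coding genes. Chromosome 14 holds 69 of the genes higher in ko.

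**Figure D4:**
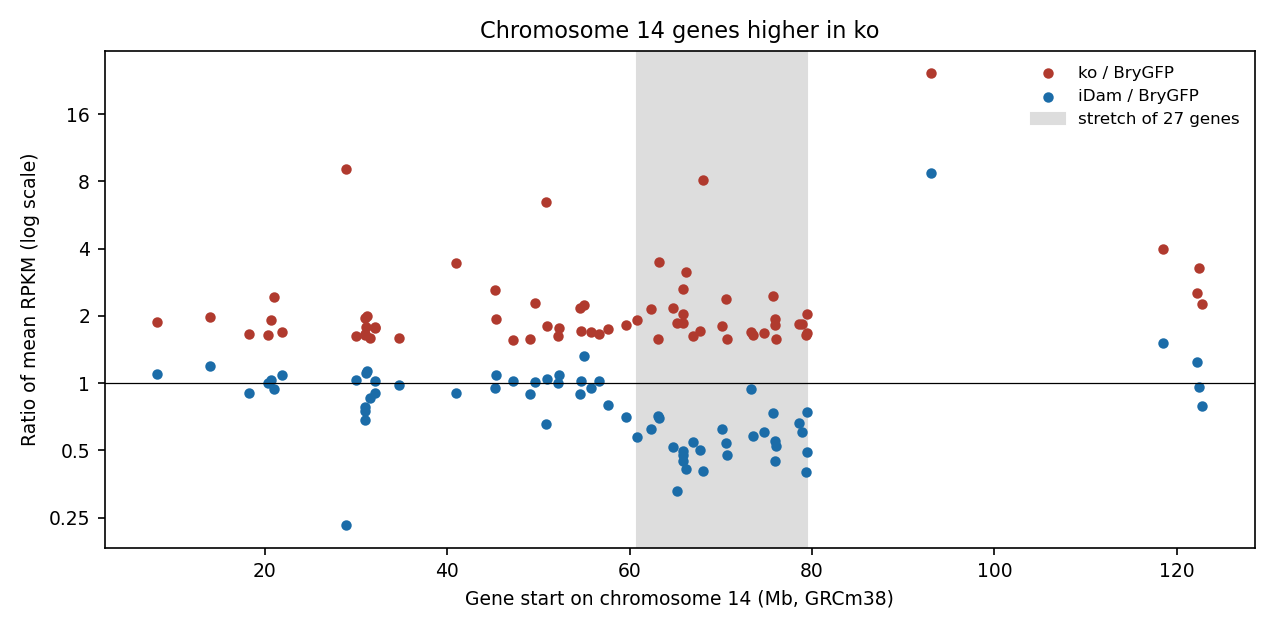
Ratios of mean RPKM, ko to BryGFP (red) and iDam to BryGFP (blue), on a log scale, by position on chromosome 14 (GRCm38) for genes higher in ko with a value above 0 in both wt lines, each point 1 gene. In the grey stretch of 27 genes the median iDam ratio was 0.539, and over the chromosome the median ko ratio was 1.84.

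In the comparison of all ko with all wt libraries by limma, the integrin genes Itga3 and Itgb3, the matrix protease gene Mmp2 and Gfi1 fell, while the integrin gene Itgb2 rose by 1.06 ± 0.27 (SE; adjusted p = 0.00386). Itga3 had a log2 difference of −2.14 ± 0.20 (SE; adjusted p = 7.41e-05), Mmp2 of −2.21 ± 0.22 (adjusted p = 9.04e-05), Itgb3 of −2.04 ± 0.35 (adjusted p = 0.000640) and Gfi1 of −1.58 ± 0.29 (adjusted p = 0.000916). Grb10 had the lowest value among these, −6.08 ± 0.17 (adjusted p = 3.91e-08). Among genes that rose, Fst had a log2 difference of 4.11 ± 0.32 (adjusted p = 4.19e-05), Nefl of 3.21 ± 0.33 (adjusted p = 9.10e-05) and Spnb1 of 2.82 ± 0.29 (adjusted p = 9.04e-05). All 360 genes tested passed, 156 higher and 204 lower in ko, which the selection of the genes on these libraries makes near certain. Under quantile normalization 281 passed, 154 higher and 127 lower, and the median log2 difference moved from −0.83 to −0.18, a shift of 0.65. Of the genes that passed, 43.3% were higher in ko with RPKM as deposited and 54.8% after quantile normalization. Quantile normalization gave all libraries the same distribution over these 360 genes alone. All of them had been selected as differing and 204 were lower in ko, so it raised ko against wt by construction. The changed balance and the calls lost under it, here and below, therefore cannot tell an unstable call from this selection. In all 18 lists with a tested member, every such member passed over all genes and also adjusted over the list alone, which is not independent evidence. Since 4 libraries of a genotype came from 2 lines, line means were also used as replicates. The ko lines need not be independent, as the labels do not say which lines share a parent line. Same-numbered ko libraries differed by a median of 0.136 and 0.138 on the log2 scale, less than libraries within iDamko (0.245) and within Ainv18ko (0.294). With line means, Acvrl1 (adjusted p = 0.0677), Cdh11 (0.0960), Clec14a (0.0747), Nnat (0.145), Pdgfrb (0.0802) and Tubb3 (0.0542) missed the threshold. Under quantile normalization Cdh11 (adjusted p = 0.0560), Clec14a (0.116), Ikzf2 (0.102), Mfng (0.178), Nnat (0.0775), Nrarp (0.217) and Pdgfrb (0.0636) missed it.

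The iDamko and iDam lines share a name stem and form the closest ko and wt pair by label. In iDamko, Itga3 was at 3.36 ± 0.345 RPKM against 16.9 ± 3.02 in iDam (SD, n = 2), and Mmp2 at 5.20 ± 0.449 against 34.2 ± 3.66 (SD, n = 2). By limma the log2 differences were −2.03 ± 0.22 for Itga3 (SE; adjusted p = 5.90e-05), −2.50 ± 0.24 for Mmp2 (adjusted p = 3.53e-05), −2.17 ± 0.29 for Cldn5 (adjusted p = 0.000161) and −1.36 ± 0.19 for Itgb3 (adjusted p = 0.000223). Tubb3 rose by 4.17 ± 0.48 (adjusted p = 7.08e-05) and Fst by 4.15 ± 0.45 (adjusted p = 5.90e-05). Of the 360 genes, 357 passed, 154 higher and 203 lower in iDamko, and under quantile normalization 283 passed, 151 higher and 132 lower. The fall of Gfi1, −1.06 ± 0.17 (adjusted p = 0.000431), and that of Pdgfrb, −0.94 ± 0.30 (adjusted p = 0.0128), missed the threshold under quantile normalization, at adjusted p = 0.190 and 0.576. Leaving out the iDam library numbered 1 or the iDamko library numbered 2 also ended the call for Pdgfrb (0.110 and 0.0628).

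Ainv18ko and BryGFP differ in line as well as in genotype, as iDamko and iDam may too. In Ainv18ko, Itgb3 was at 0.241 ± 0.109 RPKM against 7.24 ± 0.923 in BryGFP (SD, n = 2), Gfi1 at 0.328 ± 0.0575 against 4.66 ± 0.253 (SD, n = 2), and Fst at 25.2 ± 17.6 against 0.384 ± 0.0697 (SD, n = 2). By limma the log2 differences were −2.73 ± 0.19 for Itgb3 (SE; adjusted p = 3.31e-06), −2.09 ± 0.17 for Gfi1 (adjusted p = 7.03e-06), −2.76 ± 0.25 for Cdh11 (adjusted p = 1.77e-05) and 4.06 ± 0.45 for Fst (adjusted p = 4.78e-05). Of the 360 genes, 354 passed, 152 higher and 202 lower in Ainv18ko. The number higher fell to 96 without the BryGFP library numbered 2 and to 99 without the Ainv18ko library numbered 2, and under quantile normalization 277 passed, 154 higher and 123 lower. The calls in common with iDamko against iDam were 352, where independent calls at these counts would give 351. All 360 genes had the same direction in both pairs, which is no replication, since the table holds only genes with 1 direction against both wt lines. Clec14a, at −0.63 ± 0.23 (adjusted p = 0.0248), turned to 0.02 under quantile normalization (adjusted p = 0.928), a move of 0.65 where the median move of the 360 genes was 0.53 (quartiles 0.26 and 0.69), and the fall of Cldn5, −1.14 ± 0.29 (adjusted p = 0.00543), had an adjusted p of 0.0945 there and of 0.0505 without the BryGFP library numbered 2.

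The log2 difference between ko and wt differed in size between the pairs for some of these genes. The imprinted gene Nnat fell by 0.79 in iDamko against iDam and by 4.91 in Ainv18ko against BryGFP on the log2 scale, and Cdh11 fell by 0.75 and by 2.76. The ko lines were close for both genes. Nnat was at 0.104 RPKM in iDamko and 0.0682 in Ainv18ko, against 0.949 in iDam and 31.6 in BryGFP. Cdh11 was at 1.43 and 1.53, against 3.10 and 16.3. For these genes the difference between the pairs came mainly from the wt levels. In the iDam pair the values under quantile normalization were 0.12 for Nnat (adjusted p = 0.609) and −0.18 for Cdh11 (0.562), and leaving out the iDam library numbered 1 or the iDamko library numbered 2 ended both calls (0.110 and 0.0520 for Nnat, 0.0915 and 0.0814 for Cdh11). The short Rian entry ENSMUSG00000084691 (109646129 to 109646202), in the imprinted Dlk1-Dio3 locus on chromosome 12, fell by 7.47 and by 4.97. This entry was at 0 in both iDamko libraries, so its fall of 7.47 is set by the iDam level and the added 1. The other Rian entry, ENSMUSG00000091793, went from 21.9 RPKM in iDam to 0.003 in iDamko, and from 44.7 in BryGFP to 1.28 in Ainv18ko. On the log2(RPKM + 1) scale these falls were of similar size, but adding 1 compresses the gap between 0.003 and 1.28. Both entries were thus lower in iDamko than in Ainv18ko. By limma's test of the difference itself, the adjusted p was 0.000246 for Nnat, 0.0105 for Cdh11 and 0.00175 for the short Rian entry ENSMUSG00000084691. The difference passed for 35 of 360 genes, 22 with a higher and 13 with a lower log2 effect in the iDam pair. With a pseudocount of 0.1 this balance turned, to 13 higher and 19 lower. Adjusted over the list alone, 3 of 3 cell-cell adhesion molecules passed against 2 of 3 over all genes. The count also rose for the endothelial list (2 against 1) and for the Notch, cytokine receptor and pluripotent lists (1 against 0 each). The count of 35 fell to between 15 and 25 when single libraries were left out, and all of these differences compare lines as well as genotypes.

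The wt lines differed in Acta2, Cdh11, Nnat, Clec14a and Acvrl1, among other genes. Acta2 was at 128 ± 8.92 RPKM in iDam and 540 ± 132 in BryGFP, Cdh11 at 3.10 ± 0.462 and 16.3 ± 4.93, and Nnat at 0.949 ± 0.599 and 31.6 ± 6.94 (SD, n = 2 each). Clec14a was higher in iDam, at 14.8 ± 3.30 RPKM against 4.83 ± 1.05, as was the TGF-beta family receptor gene Acvrl1, at 40.0 ± 1.42 against 13.1 ± 0.843 (SD, n = 2 each). By limma the log2 differences of iDam from BryGFP were −2.05 ± 0.29 for Acta2 (SE; adjusted p = 0.00174), −4.08 ± 0.25 for Nnat (adjusted p = 1.37e-05), 1.44 ± 0.23 for Clec14a (adjusted p = 0.00244) and 1.54 ± 0.22 for Acvrl1 (adjusted p = 0.00174). Neither the contractile gene Myl9 (−0.31 ± 0.27; adjusted p = 0.520) nor the endothelial gene Aplnr (0.67 ± 0.40; adjusted p = 0.312) passed. Of 360 genes, 91 passed, 22 higher and 69 lower in iDam, and under quantile normalization 87 passed, 31 higher and 56 lower. Adjusted over the list alone, 3 of 4 integrins passed against 2 of 4 over all genes, and 2 of 2 neural genes against 1 of 2. The count was 50 without the iDam library numbered 1 in the column names, 55 without the iDam library numbered 2 and 42 without the BryGFP library numbered 2.

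Between the ko lines, most of the tested genes that passed lay in the Dlk1-Dio3 locus on chromosome 12. Rian (ENSMUSG00000084691) was listed at 0 in both iDamko libraries and was at 7.45 ± 1.51 RPKM in Ainv18ko (SD, n = 2), against 177 ± 27.2 in iDam and 262 ± 31.8 in BryGFP (SD, n = 2 each). Acta2 was also lower in iDamko than in Ainv18ko, with a log2 difference of −1.52 ± 0.29 (SE; adjusted p = 0.0190, limma), and H19 higher, at 1.24 ± 0.28 (adjusted p = 0.0448). Of 360 genes, 13 passed by limma, 1 higher and 12 lower in iDamko, and 19 had an unadjusted p under 0.05. Of the 13, 11 were transcripts of the locus. The median absolute log2 difference was 0.10 between the ko lines, 0.31 between the wt lines and 1.12 between ko and wt. The selection of the table favours this order, since each of its comparisons took the 4 ko libraries as 1 group. Same-numbered ko libraries also deviated together (r = 0.69), and those of the wt lines did not (−0.20). A shared deviation cancels between the ko lines, and this fit did not pair libraries. The values and counts for ko and wt lines are therefore not like for like. The call for Acta2 was lost on leaving out either iDamko library (adjusted p = 0.0636 and 0.169) or the Ainv18ko library numbered 1 (0.144), and under quantile normalization (0.153). That for H19 was lost with no filter (0.108) and on leaving out any of 7 libraries, with adjusted p from 0.0528 to 0.342.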

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

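Every test of an explanation in this part was chosen only after the result was seen. Groups of 4 libraries of 1 genotype were searched for a library far from the other 3, which chance alone finds in about 1 in 20 groups. In 142 groups 5 were found, where 7.1 are expected by chance. An iDamko library had Angpt2 at 0.529 RPKM, against 0.318 to 0.345 in the other ko libraries. An Ainv18ko library had Foxa2 at 2.94 RPKM, against 1.23 to 1.39. An iDamko library had Il1r1 at 1.76 RPKM, against at most 1.37. An Ainv18ko library had Lst1 at 0, against 0.104 to 0.125 RPKM. An Ainv18ko library had Lyz2 at 0.0171 RPKM, against 0 in the others.

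For 15 named genes, limma's test of the difference between the ko effects passed the threshold. Each difference below is the log2 effect of iDamko against iDam minus that of Ainv18ko against BryGFP, followed by its adjusted p and the effects in that order. Of the Dlk1-Dio3 transcripts, AF357425 differed by −4.02 (0.000246; −7.93 and −3.91), SNORD113 ENSMUSG00000084549 by −3.70 (0.000246; −8.30 and −4.60) and SNORD113 ENSMUSG00000084487 by −3.55 (0.00175; −7.75 and −4.20). AF357355 differed by −2.61 (0.00178; −6.77 and −4.16) and Rian ENSMUSG00000084691 by −2.50 (0.00175; −7.47 and −4.97). All of these locus transcripts were at 0 in both iDamko libraries. The sizes of their effects in the iDam pair, and of the differences, are thus set by the iDam level and the added 1. Clec14a differed by −1.53 (0.0222; −2.15 and −0.63) and Acvrl1 by −1.41 (0.0260; −2.25 and −0.85). Gfi1 differed by 1.03 (0.0260; −1.06 and −2.09), Itgb3 by 1.37 (0.0172; −1.36 and −2.73), Pdgfrb by 1.79 (0.0284; −0.94 and −2.73) and Cdh11 by 2.01 (0.0105; −0.75 and −2.76). Of the imprinted genes, Mir675 differed by 1.98 (0.0159; −2.89 and −4.88), H19 by 2.34 (0.00787; −2.62 and −4.96) and Nnat by 4.13 (0.000246; −0.79 and −4.91). Tubb3 differed by 2.76 (0.0330), with effects of 4.17 and 1.41. Outside the locus, H19 and Mir675, these genes had similar levels in the ko lines and differing levels in the wt lines. Acvrl1 was at 7.59 RPKM in iDamko and 6.97 in Ainv18ko, against 40.0 in iDam and 13.1 in BryGFP. Itgb3 was at 0.268 and 0.241, against 2.24 and 7.24. Their differing effects thus rested mainly on the wt levels. With a pseudocount of 0.1 the adjusted p was 0.154 for Gfi1, 0.134 for Itgb3 and 0.103 for Pdgfrb, and with no filter it was 0.0513 for Pdgfrb and 0.0607 for Tubb3. Leaving out 1 library ended the call for Gfi1 with 7 of the 8 libraries (adjusted p up to 0.103), Acvrl1 with 6 (0.0962), Tubb3 with 6 (0.108), Clec14a with 4 (0.0723), Pdgfrb with 4 (0.110), Itgb3 with 3 (0.0723) and Mir675 with 2 (0.0535).

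At the Dlk1-Dio3 locus on chromosome 12 (109541001 to 109743795, GRCm38), 46 of 49 transcripts were at 0 in both iDamko libraries and 21 in both Ainv18ko libraries. Reads shared between SNORD113 copies are argued against, since the 34 other transcripts kept a median of 0.563% of the BryGFP level in Ainv18ko and 0 of the iDam level in iDamko. Wt cells or reads mixed into the Ainv18ko libraries could leave such a remnant, and the count of genes set as a test did not decide. Of 99 genes outside the locus, 2, Nnat and Grb10, lay more than 3 times below the level that mixing would bring, under the 3 genes set as the bound. Grb10 was at 0.450 RPKM in Ainv18ko, where the median of 2.87% kept by the 29 locus transcripts of at least 5 RPKM in BryGFP would bring 3.09, and Nnat at 0.0682 where it would bring 0.904. Grb10 was high in both wt lines, at 108 RPKM in BryGFP and 92.1 in iDam, and kept 0.417% of its BryGFP level. This value, from Grb10 alone, argues against mixing as the source of the 2.87%. The median of 0.563% kept by the 34 other transcripts lies near it, so mixing stays open for transcripts at such shares. Of the 49 locus transcripts, 21 were at 0 in both Ainv18ko libraries, which lowers such a median. Among the 34, AF357425 (29.2 RPKM in Ainv18ko, 442 in BryGFP) and Rian ENSMUSG00000091793 (1.28 and 44.7) kept a larger share than Grb10. The argument from Grb10 covers these as well. Runx1 loss and the separate history of each line may both explain the fall and cannot be told apart, as 11 of 36 tested transcripts of the locus differed between the ko lines and the labels do not say which lines share a parent line.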

How the results depend on the processing

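The block, the authors' scaling, the counts without chromosome 14 and, outside ko against wt, quantile normalization, the pseudocount and leaving out single libraries were chosen after seeing the data. All 360 genes passed for ko against wt, 622 with no filter and 220 with an absolute log2 difference of at least 1 (80 higher, 140 lower), changes that follow from which genes were counted. Leaving out single libraries gave 351 to 368. For iDamko against iDam, 357 passed, 591 with no filter and 305 to 368 without single libraries. For Ainv18ko against BryGFP it was 354, 582 with no filter and 240 to 363. The difference between the ko effects passed for 35 genes (83 unadjusted), and for 15 to 25 without single libraries. Between iDam and BryGFP 91 passed (125 unadjusted), and 42 to 96 in refits without single libraries, and between the ko lines 13 passed, and 9 to 13 in such refits, with fewer libraries behind each. A line left with 1 library is assumed to vary like the others. In the authors' deposited table, 387 genes were lower and 235 higher in ko, 153 and 158 above the median level, and 270 and 139 at FDR 0.01. Fewer genes are counted there by construction, and why the lower genes lost more above the median was not tested. Under quantile normalization the log2 difference of Clec14a in Ainv18ko against BryGFP went from −0.63 to 0.0238, a move of 0.65 that lies within the quartiles of the moves of all 360 genes (0.26 and 0.69). That of Nnat in iDamko against iDam went from −0.79 to 0.123, where the quartiles were 0.15 and 0.57, and the cause was not tested. No gene list passed Benjamini-Hochberg adjustment under any setting, and the matrix list's p of 0.164 became 0.0561 above the median level and 0.350 without chromosome 14. For named genes, 899 of 918 alternative values kept their call for ko against wt, 770 of 799 for iDamko against iDam, 820 of 846 for Ainv18ko against BryGFP, 158 of 195 for the difference, 284 of 323 between the wt lines and 79 of 91 between the ko lines. With a replicate block from the column names, the difference between the ko effects passed for 53 genes (32 higher, 21 lower), and the cause was not tested. The block gave 359 for ko against wt, 359 for iDamko against iDam, 357 for Ainv18ko against BryGFP, 110 between wt lines and 13 between ko lines. Same-numbered libraries deviated together for iDam with iDamko (r = 0.41), iDam with Ainv18ko (0.52) and iDamko with Ainv18ko (0.69), but not for BryGFP with iDam (−0.20), iDamko (−0.03) or Ainv18ko (0.01), so the numbers were not taken as pairs of all lines. The median absolute log2 difference was 0.136 and 0.138 between same-numbered libraries of the 2 ko lines, against 0.245 within iDamko and 0.294 within Ainv18ko. A block by the numbers of the sample titles was not possible because the columns do not carry them. Fits with DESeq2, size factors and that block were not run, nor was Runx1 with a library left out. Depth, known only as implied, limits genes listed at 0.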

Other observations

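The 4 gene groups below, the genes named for them or for values of 0, the stretch of chromosome 14 and every test in this part were chosen only after the values were seen. Homeobox genes of the Hox and Cdx families went in 1 direction, with 17 lower and 0 higher in ko (Fisher's exact test against the other genes of the table, p = 0.000459, Benjamini-Hochberg p over the 4 groups 0.000918). Hoxd8 was at 10.6 ± 2.47 RPKM in wt and 2.62 ± 0.707 in ko (SD, n = 4), a log2 difference of −1.68 ± 0.20 (SE; adjusted p = 0.000183, limma). Hoxb2 had a log2 difference of −1.41 ± 0.22 (SE; adjusted p = 0.000500, limma), and Hoxb4 was at 2.62 ± 0.559 and 0.947 ± 0.391 RPKM (SD, n = 4; −0.90 ± 0.18; adjusted p = 0.00141). Cdx2, below the filter on level, was at 1.57 ± 1.28 RPKM in wt and 0.0563 ± 0.0501 in ko (SD, n = 4). In each of the groups here, picked after their direction was seen, neighbouring genes are not independent, so the p-values describe only the counts.

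Interferon-inducible GTPase, Schlafen and Gimap genes were also all lower in ko, 10 against 0 (Fisher's exact test, p = 0.0161, Benjamini-Hochberg p = 0.0161). Irgm1 was at 2.23 ± 0.618 RPKM in wt and 0.425 ± 0.0627 in ko (SD, n = 4; log2 difference −1.16 ± 0.16, SE; adjusted p = 0.000287), and Gimap4 at 12.7 ± 7.58 and 3.27 ± 0.564 (adjusted p = 0.00442). Of imprinted genes 14 were lower and 0 higher, with Meg3, Mirg and Rian of the Dlk1-Dio3 locus among them (Fisher's exact test, p = 0.00147, Benjamini-Hochberg p = 0.00196). All 49 transcripts of that locus in the table were lower. Ndn was at 35.5 ± 1.75 RPKM in wt and 18.9 ± 2.83 in ko (SD, n = 4; −0.89 ± 0.14, SE; adjusted p = 0.000490, limma), and Peg12 had a log2 difference of −0.94 ± 0.19 (adjusted p = 0.00129). Under quantile normalization the adjusted p was 0.433 for Hoxb4, 0.0837 for Irgm1, 0.0607 for Gimap4 and 0.270 for Peg12, and with line means as replicates it was 0.0671 for Gimap4. Listed at 0 in all 4 ko libraries were 24 genes, Mc5r and Podnl1 among them, and at 0 in all 4 wt libraries were Alox12b and Nrg2.

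Of the 35 splits of the 8 libraries into 4 and 4, only 1, the real split, gave as many genes as the 360 of ko against wt, and the highest other split gave 0. Because the genes had been selected on the real split, this cannot tell chance from an effect.

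Of the 69 genes of chromosome 14 higher in ko, 68 with a ratio spanned 94.3% of it, from 8165996 to 122913757 (GRCm38). Their median ratio of ko to BryGFP RPKM was 1.84 (quartiles 1.67 and 2.24), against 3.15 over 158 genes higher in ko elsewhere. An additional copy of the chromosome in both ko lines could account for them only in part or with the selection of the genes, since it would bring a ratio of 1.5, below the median and lower quartile seen, and the smallest folds in the authors' deposited table, 1.62 against iDam and 1.53 against BryGFP, leave lower ratios out. Runx1 loss acting on separate genes is argued against for the excess as a set (Fisher's exact test, Benjamini-Hochberg p = 2.68e-26, next highest chromosome 7.23%). Single genes such as Gata4, Nefl and Cacna2d3, and the chromosome number itself, stay open, since no DNA was analysed here.

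In the stretch of chromosome 14 from 60784573 to 79423587, all 27 genes were lower in iDam than in BryGFP, with a median ratio of 0.539 against 0.998 over 41 genes outside. Chance order of the genes is argued against by a share of 0.0001 of shuffled orders with such a stretch, the smallest that 10000 shuffles can give. The ratio of ko to iDam was 3.39 inside and 1.85 outside, 1.84 times as high. The stretch was chosen by its low ratios of iDam to BryGFP, among genes selected as higher in ko than in BryGFP. Together these choices favour a high ratio of ko to iDam, so that ratio adds no support for a cause. A lost copy in iDam could account for the values: it would bring a ratio to BryGFP of 0.5, within the quartiles (0.478 and 0.616). A gained copy in BryGFP would bring 0.667, outside those quartiles, but it is not ruled out, since the ratio of ko to BryGFP, 1.86 inside and 1.80 outside, leaves out genes that such a gain brought to the BryGFP level. Which of these holds, and what share of the ko effect it brings for genes of the stretch, stays open.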
